A study of Mus musculus with 4 samples.

How the data were processed

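Messenger RNA was measured in 4 libraries of mouse embryonic stem cells, 2 of cells without the miR-290 to miR-295 cluster and 2 of wild-type cells. Per the labels' protocols, RNA was extracted with Trizol, and poly(A) RNA was made into libraries with the QuantSeq 3' FWD kit, in which each read lies near the 3' end of a transcript. The authors deposited 1 table of raw counts per Ensembl gene identifier, with no normalization, and the values are whole numbers. Trim Galore and the build GRCm38 are named in the submitters' processing notes. The aligner, the counting program, its strand setting and the annotation release are not given in the sources used here. Reads of overlapping genes, and of paralogs, could therefore be split in ways that the table does not record. At the cluster, WT library 1 held 80 counts on Mir295 and 0 on the antisense gene Nlrp12, whose last exon contains it.

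Genes were named and placed with GENCODE vM21 (GRCm38). Of 55421 identifiers, 55154 were in it and 267 had no name, which together held 0.0118% of all counts. At least 1 count was present for 25542 genes. A chi-square comparison of counts gave 8.29 per degree of freedom for the KO pair and 13.2 for the WT pair, against 25.7 to 31.8 between groups, so no library repeats another. Depth sets a floor: 3 counts correspond to between 0.236 and 0.302 CPM per library, and to 0.122 CPM over the KO group and 0.136 over the WT group. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

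Groups came from the titles of the samples. KO was compared with WT by edgeR 4.0.16 (quasi-likelihood F test, two-sided, in R 4.3.3) with TMM normalization, filterByExpr and Benjamini-Hochberg adjustment over the 14427 genes that passed, at an adjusted p of 0.05. The biological coefficient of variation was 0.198. Standard errors are the log2 fold change divided by the square root of F. CPM values are on the TMM scale and are given as mean ± SD. The 26 gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 26 lists. An estimated correlation was the alternative, and that test rests on 2 residual degrees of freedom. fry asked whether a list moved, on balance, one way, and gave adjusted p-values of 0.00441 for primitive endoderm, 0.0317 for the unfolded protein and integrated stress response, 0.058 for germline genes and 0.139 for the 2-cell-like state.

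For seed matches, 3' UTRs were taken from GENCODE transcripts for 21003 genes, of which 12483 were tested. The longest 3' UTR of each gene was searched for AGCACTT, GCACTTA, AGCACTTA and GCACTT, and for control sites. Camera compared site genes with genes without GCACTT, with the main set fixed as the 7-base sites, and p-values were adjusted over the 12 site tests after the data were seen. The exact permutation of library labels, two-sided and also added then, ran over all 6 splits. For the 7-base and 8-base sets 10000 random sets were drawn from a grid of 3' UTR length and expression. The rank of GCACTT among 4096 words came from a linear model with 3' UTR length, GC content and expression as covariates, with fold changes limited to 3 on the log2 scale (Python 3.11.15, numpy 2.4.6).

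Named genes followed a rule: the genes of the locus with any count, the 12 higher and 12 lower genes with the largest change among those called, with a mean CPM of at least 5 and both KO libraries on the same side of both WT libraries, up to 4 members with the smallest p of each list, all tested literature targets, and Tfap4. Pdgfra, Cubn, Hnf4a, Sox17, Lamb1, Hspa5, Phgdh, Psat1, Chac1, Tex101, Gata4, Sox7, Foxa2, Lamc1, Sparc, Rpl10l, Psmb9 and B2m are outside it and were chosen after their values were seen. The same holds for Asns, Ddit3, Atf4, Sesn2, Hsp90b1 and Dnajb9. Groups, the main tests, the lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0 size factors, the DESeq2 test, no filter, a mean CPM of at least 10, the replicate number as a block, thinning to equal depth, each library left out, and other definitions of sites, 3' UTRs, background and correlation. Leaving out chromosome 1, removing chromosome medians and leaving out small non-coding and mitochondrial genes were added after the data were seen.

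The scripts were tested on simulated counts for the comparison of KO with WT, drawn from the real means, depths and dispersions, with 200 genes changed. After the filter 14085 genes were tested. The test recovered 5.97% of genes changed 1.5-fold, 34.3% of those changed 2-fold and 84.8% of those changed 4-fold, and called 0.0353% of unchanged genes. A planted site shift of 0.2 was measured as 0.215. The 200 genes were taken from those with a mean of at least 2 CPM, so these shares do not cover lower genes. In a separate draw with no change simulated, where 14114 genes were tested, 1 gene and 0 lists were called. Genes were drawn independently of each other, so the list result does not test the preset correlation.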

Results

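Transcript levels were measured in mouse embryonic stem cells of the E14 line, derived from the blastocyst of a 129/Ola mouse and grown in serum with the cytokine LIF on gelatin. Cells that lack the miR-290 to miR-295 cluster (KO, n = 2 libraries) were compared with wild-type cells (WT, n = 2 libraries). The cluster encodes the most abundant microRNAs of mouse embryonic stem cells, and several of them share the seed AAGUGC. Libraries were made with a 3' tag method (QuantSeq), in which each transcript gives reads near its poly(A) tail. The deposited count table held 12726123 and 11764868 counts for KO libraries 1 and 2, and 12163759 and 9925557 for WT libraries 1 and 2, over 55421 gene identifiers. The design text calls the libraries biological duplicates, and the labels do not say whether the KO libraries come from separate clones, so p-values measure the spread between these libraries.

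The first comparison was at the deleted locus, as a check of the labels. The microRNA genes of the cluster lie on chromosome 7 of GRCm38, between 3218626 and 3220841, and 7 of them are on the plus strand. These 7 genes held 88 counts in WT library 1 (95% Poisson interval 70.6 to 108) and 39 in WT library 2 (27.7 to 53.3), and 0 in each KO library (upper bound 3.69). Mir295 (ENSMUSG00000077886, 3220773 to 3220841) carried most of them, with 80 and 22 counts in WT, and was at least 35.9-fold lower in KO against a floor of 3 counts over the group (edgeR adjusted p = 0.00544). The other plus-strand microRNA genes held at most 7 counts in any library, too few to show the loss of each. Mir291a held 0 in every library. On the minus strand, Mir292b held 0 in every library, and Mir290b held 4 in KO library 1 and 0 in the others. A library of poly(A) tags detects the precursor transcript, not the mature microRNA. The neighbours AU018091, Myadm and Cacng7 did not pass the test, with log2 fold changes (KO over WT) of 0.01 (SE 0.17), -0.48 (SE 0.27) and -0.67 (SE 0.27). With 1 library left out Myadm and Cacng7 moved: Myadm gave -0.96 without KO library 2 (edgeR adjusted p = 0.0468), -0.71 without WT library 2 (adjusted p = 0.0494), -0.11 without KO library 1 and -0.22 without WT library 1. Cacng7 gave -1.15 without KO library 2 (adjusted p = 0.0341) and -0.31 without KO library 1. A lower level of both is not excluded. Nlrp12 is a minus-strand gene whose last exon (3218784 to 3222560) spans 7 of the 9 microRNA genes of the cluster, and it held 161 counts in KO library 1, 0 in KO library 2, 0 in WT library 1 and 1 in WT library 2.

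The main comparison asked which transcripts change when the cluster is lost. Cells without the cluster had much more RNA of the cell cycle regulator cyclin D2 (Ccnd2, 453 ± 58.2 CPM in KO and 17 ± 1.23 in WT, SD, n = 2), of the Nodal antagonists Lefty1 and Lefty2, and of Hhip, which encodes a Hedgehog-binding protein. They had less RNA of genes of the primitive endoderm, the extraembryonic lineage that lines the blastocyst cavity, such as Dab2, Gata6 and the basement membrane collagen Col4a1. Of 14427 genes tested, 1071 were higher in KO (7.42%) and 715 were lower (4.96%) at a Benjamini-Hochberg adjusted p below 0.05 in edgeR's quasi-likelihood test, and 737 and 475 of these differed at least 2-fold. Every called gene had both KO libraries on the same side of both WT libraries. Over all tested genes 57.9% did, where chance gives 33.3%. Without KO library 1 the counts were 586 and 285, and without KO library 2 they were 556 and 319, with the lone KO library assumed to vary like the WT pair.

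**Figure D1:**
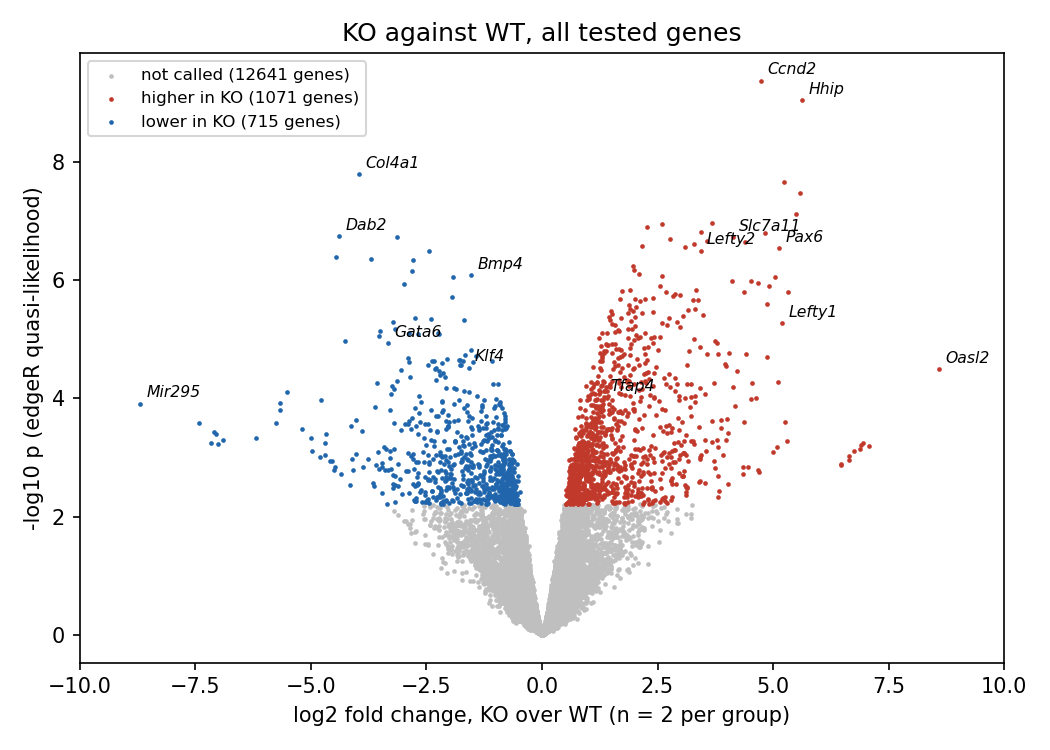
Log2 fold change (KO over WT, horizontal axis) against -log10 of the unadjusted p of edgeR's quasi-likelihood test (vertical axis), one point per tested gene. The 1071 genes higher in KO are red, the 715 lower genes are blue, and genes named in the text are labelled.

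Among called genes with a mean CPM of at least 5, the 12 higher genes with the largest changes had log2 fold changes between 4.73 and 5.63. Hhip rose by 5.63 (SE 0.24, adjusted p = 6.67e-06), from 2.05 ± 0.0608 CPM in WT to 102 ± 10.7 in KO. Inhbe, an inhibin beta subunit, rose by 5.58 (SE 0.34), the cytochrome P450 gene Cyp4f40 by 5.50 (SE 0.37), and Serpinf1, which encodes a secreted serpin, by 5.24 (SE 0.31). The homeobox genes of the X-linked Rhox cluster Rhox9 and Rhox6 rose by 5.33 (SE 0.51) and 5.04 (SE 0.45), and such paralogs can share reads. With 1 library left out Rhox9 lay between 4.72 and 6.6 and Rhox6 between 4.34 and 5.65. Pax6, a neural and eye transcription factor, rose by 5.12 (SE 0.40) to 16.2 ± 0.351 CPM. The rest were Cdk15 with 4.90, Adh7, an alcohol dehydrogenase, with 4.86, the G protein subunit Gna14 with 4.83, and Ccnd2 with 4.73 (SE 0.18, adjusted p = 6.2e-06). Cdk15 gave 4.17 without WT library 1 and 6.16 without WT library 2. Lefty1, also in this set, rose from 5.45 ± 5.87 to 206 ± 14.6 CPM, and its log2 fold change was 7.30 without WT library 1, in which it held 115 counts against 13 in WT library 2.

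Among the 12 lower genes chosen with the same CPM limit, Dab2, an endocytic adaptor, changed by -4.38 (SE 0.33), Col4a1 by -3.95 (SE 0.23) and the transcription factor Gata6 by -3.33 (SE 0.40). Plac8 changed by -3.50, Usp26, an X-linked ubiquitin protease, by -3.47 (-5.37 without KO library 2 and -2.44 without WT library 2), and the homeobox gene Crxos by -3.30. Crxos rested on WT library 2, with 160 counts against 46, and gave -1.95 with an adjusted p of 0.0615 without it. The small nucleolar RNAs Snora20 and Snord13 changed by -3.69 and -3.58. Snord13 held 511 counts in WT library 1 and 1520 in WT library 2, and gave -4.22 without the first and -2.39 without the second. Gm26448 and Gm22748, annotated as small nucleolar RNAs, the long non-coding RNA D030068K23Rik and ENSMUSG00000051412, which has no name in the annotation, made up the rest. Of 68 snoRNA genes tested, 31 were lower and 0 higher (75 of 715 lower genes were not protein coding). All small non-coding RNA outside the mitochondria took 0.0726% and 0.0661% of counts in KO and 0.144% and 0.152% in WT.

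Known targets of the seed family were examined as a list drawn from the literature. Lefty1 and Lefty2 (3.43, SE 0.27, adjusted p = 0.000205), the p53-induced gene Ei24 (0.83, SE 0.19) and the methyl-CpG binding protein gene Mbd2 (0.90, SE 0.21) rose, and 0 of the 15 tested members fell. Lefty1 and Lefty2 are close paralogs on chromosome 1, so reads may have been split between them, and the genes of that chromosome had a median of 0.29, next to -0.28 for WT library 1 over WT library 2. The other 11 members did not pass: Tgfbr2 (1.36), Casp2 (0.82), Ash1l (0.58), the CDK inhibitor Cdkn1a (0.53), Lats2 (0.25), Rbl2 (0.24), Arid4b (0.13), Wee1 (-0.05), Fbxl5 (-0.31), Rhoc (-0.66) and Dkk1 (-1.91). Without KO library 2 Ei24 gave 0.71 (edgeR adjusted p = 0.17) and Mbd2 1.01 (0.0808), and without KO library 1 Mbd2 gave 0.81 (0.192). Without WT library 1 Casp2 (1.16) and Rhoc (-0.98) passed, and without WT library 2 Cdkn1a (0.70) and Tgfbr2 (1.82). Adjusted over the list alone, 8 were higher and 2 lower. The list median was 0.53 and the camera test gave an adjusted p of 0.0879 (0.589 with an estimated correlation), and it passed without KO library 1 (median 0.78, adjusted p = 0.00934) and without WT library 1 (0.74, adjusted p = 0.0282). It did not pass without KO library 2 (0.40, adjusted p = 0.196), without WT library 2 (0.54, adjusted p = 0.119) or with chromosome 1 genes left out (0.26, adjusted p = 0.315), and it passed with the DESeq2 test (adjusted p = 0.00281), with thinned libraries (adjusted p = 0.0168) and without a low-count filter (adjusted p = 0.019). Tfap4, a bHLH transcription factor gene with an 8-base site in its 3' UTR, rose by 1.34 (SE 0.21, adjusted p = 0.00469), from 18.5 ± 2.39 to 47 ± 4.89 CPM.

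**Figure D2:**
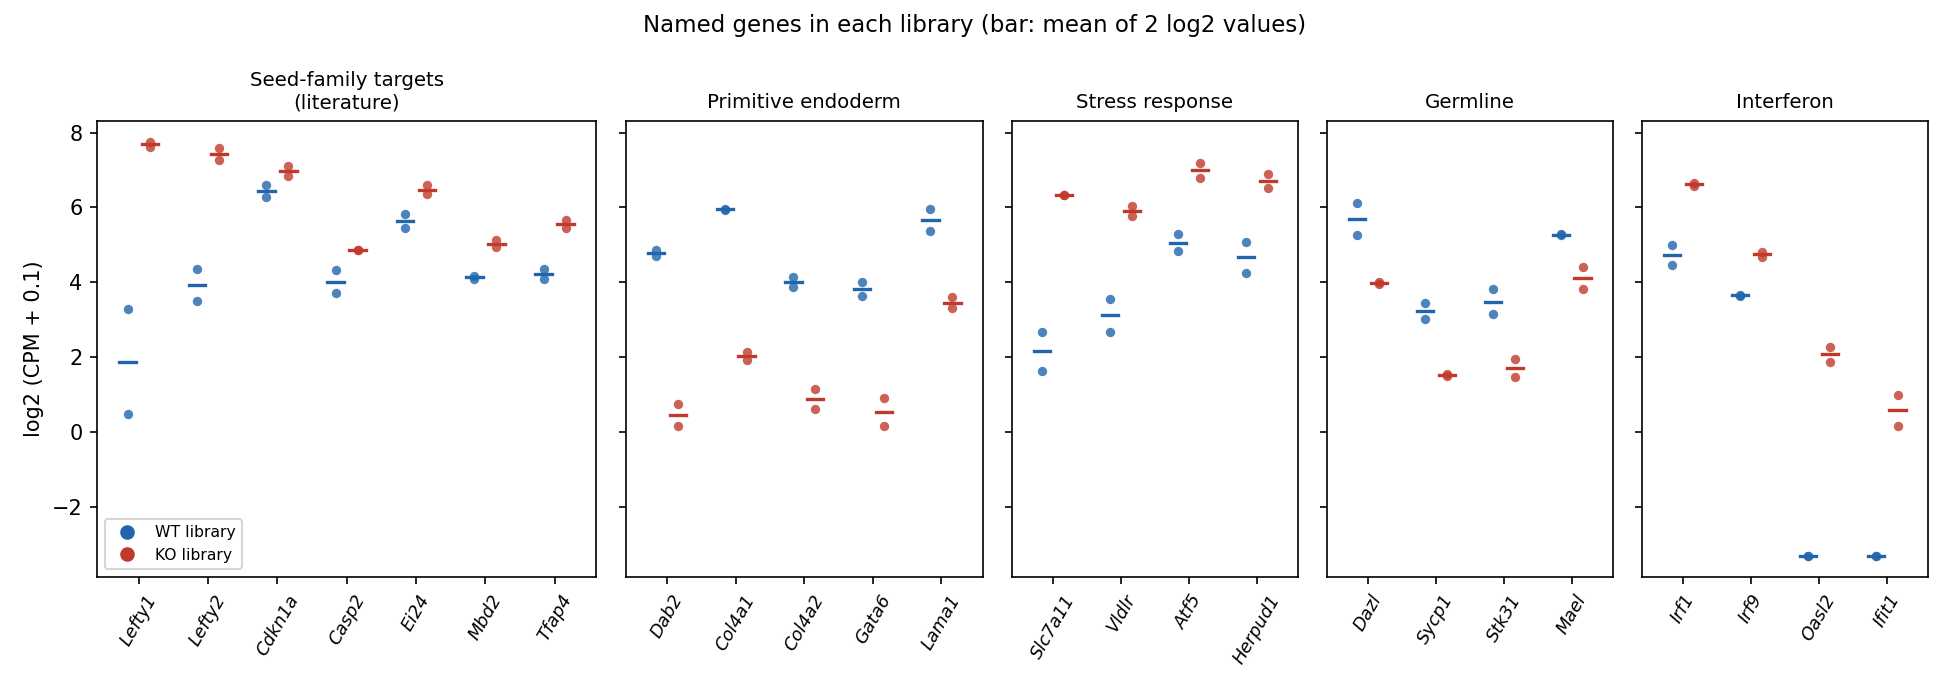
Log2 of CPM plus 0.1 (vertical axis) for chosen genes in each of the 2 KO (red) and 2 WT (blue) libraries, with bars at the mean of the 2 log2 values. List members that went the other way are not drawn, such as Psmb9 and B2m (interferon), Dkk1 and Rhoc (literature targets) and Rpl10l (germline). Tfap4 is drawn with the literature targets but is not in that list. Lefty1, Slc7a11 and Oasl2 lie higher in both KO libraries, and Dab2, Col4a1 and Gata6 lie lower in both.

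The next comparison asked whether genes that carry a match to the seed moved together. Genes with the 8-base site AGCACTTA in their longest annotated 3' UTR (432 genes) had a median log2 fold change of 0.2, against -0.0345 for 8332 genes without GCACTT, a shift of 0.235 (camera adjusted p = 0.00197 over 12 site tests). With an estimated correlation no site passed, and the 8-base site gave an adjusted p of 0.149 (0.0301 unadjusted). Genes with at least 1 7-base match, AGCACTT or GCACTTA (2604 genes), had a median of 0.11 and shifted by 0.144. For this set, fixed as the main one, the unadjusted camera test gave p = 0.0208 and the adjusted value was 0.0718, and an exact permutation of the library labels cannot go below 0.333 with 2 libraries per group. In that permutation the true labels gave a shift of 0.14 and the other ways to pair the libraries at most 0.0136. Genes with GCACTT alone (1547 genes) shifted by 0.0669 (adjusted p = 0.321). Of the genes higher in KO that have a 3' UTR, 27.6% held a 7-base site, against 20.7% of genes not called (Fisher's exact odds ratio 1.46, 95% interval 1.26 to 1.70, adjusted p over 4 tests = 1.25e-06) and 13.5% of lower genes (Fisher's exact odds ratio 0.597 against genes not called, 0.468 to 0.754, adjusted p = 6.49e-06). For 8-base sites the shares were 6.91%, 3.28% and 1.10%. Fisher's test treats genes as independent, which they are not. Among 4096 possible 6-base words, GCACTT had rank 1 by its association with higher expression in KO, after adjustment for 3' UTR length, GC content and expression level.

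The shift was seen for the KO libraries against the WT libraries taken singly (0.106 to 0.156), while WT library 1 against WT library 2 gave -0.00331 and KO library 1 against KO library 2 gave -0.0312. Of 10000 random gene sets matched on 3' UTR length and expression, 0 had a median as high as that of the 7-base set, and 0 as high as that of the 8-base set. The random sets, which can hold site genes, had mean medians of 0.0415 and 0.0498, against 0.11 and 0.2 for the site sets. Such draws treat genes as independent. The single sites GCACTTA and AGCACTT gave 0.171 (adjusted p = 0.0154, and 0.149 with an estimated correlation) and 0.143 (adjusted p = 0.0718). GGCACTT, a site of the same seed family, gave 0.132 (adjusted p = 0.0722), and GCACTTT, which matches the overlapping seed of the miR-17 family, gave 0.109 (adjusted p = 0.118). The control sites of let-7 (0.00135), miR-1 (0.097), miR-122 (0.005), miR-124 (0.0558) and miR-25/92 (-0.0365) gave adjusted p-values between 0.321 and 0.853. The unadjusted call for 7-base sites did not hold without KO library 2 (shift 0.126, p = 0.0609), with an estimated correlation (p = 0.0601), with the shortest 3' UTR (0.105, p = 0.0918), against a background matched on length and expression (0.107, p = 0.0722) or with chromosome medians removed (0.128, p = 0.0525), and the direction held in all of them.

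**Figure D3:**
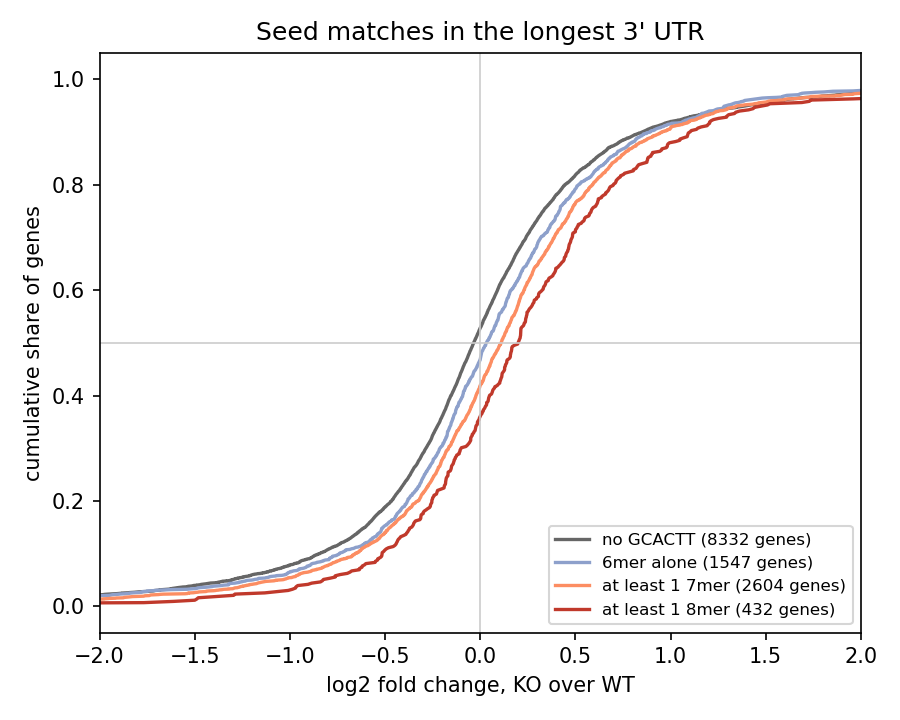
Cumulative share of genes (vertical axis) by log2 fold change, KO over WT (horizontal axis, drawn from -2 to 2), for genes with no GCACTT, the 6-base site alone, at least 1 7-base site or at least 1 8-base site in the longest 3' UTR. The curves shift to the right in that order, with medians of -0.0345, 0.0324, 0.11 and 0.2.

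Gene lists fixed before the data were examined were then compared, 26 in all. Primitive endoderm genes fell most: 12 of 17 tested members were lower and 0 higher, with a list median of -2.69. The 6 members with a mean CPM of at least 10 had a median of -1.68 (camera adjusted p = 0.00274). Besides Dab2, Col4a1 and Gata6, the 12 lower members included Col4a2 (-3.17, SE 0.36), the laminin gene Lama1 (-2.25, SE 0.26) and the receptor gene Pdgfra (-3.61, SE 0.59). Gata4, Sox7, Foxa2, Lamc1 and Sparc did not pass, with -0.65, -0.87, -1.05, 0.42 and -0.10. Lamc1 passed without WT library 2 (0.62), Foxa2 gave 0.36 without WT library 1, Sparc gave 0.18 without KO library 1 and 0.34 without WT library 2, and Sox7 lay between -1.52 and -0.41 with 1 library left out. Camera gave an adjusted p of 3.41e-09 (adjusted p = 0.429 with an estimated correlation). Adjusted over the list alone, 12 were lower and 1, Lamc1, was higher. Of the 12, Cubn (-2.78) lost its call without any 1 of the 4 libraries (-3.39 to -2.32), Hnf4a (-3.39) without KO library 1 (-3.54), KO library 2 (-3.25) or WT library 1 (-2.24). Sox17 (-2.69) and Lamb1 (-1.07) lost theirs without KO library 2 (-2.44 and -0.87). In the same libraries 3 of 5 fibroblast or feeder cell markers were lower, Thy1 (-1.34), Col5a1 (-1.10) and Col1a1 (-2.19), with a list median of -1.10 (camera adjusted p = 0.0525, and 0.589 with an estimated correlation, and 0.0235 without KO library 2, where the median was -1.23). The list also passed with thinned libraries (adjusted p = 0.0311) and without small non-coding and mitochondrial genes (adjusted p = 0.0465). None of these 3 calls held in every fit with 1 library left out, where fewer residual degrees of freedom remain. The direction held in all of them. Col1a1 lay between -2.29 and -2.09, Col5a1 between -1.23 and -0.97 and Thy1 between -1.95 and -0.85.

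Genes of the unfolded protein and integrated stress response rose, 10 of 16 members, with a list median of 0.84 (camera adjusted p = 0.000136, and 0.429 with an estimated correlation). They included the cystine transporter gene Slc7a11 (4.13, SE 0.31), Vldlr (2.75, SE 0.29), Herpud1 (2.00, SE 0.27), which acts in degradation at the endoplasmic reticulum, and Atf5 (1.94, SE 0.22), and 11 were higher when adjusted over the list alone. The other 6 members did not pass: Asns (0.39), Ddit3 (0.16), Atf4 (0.16), Sesn2 (0.15), Hsp90b1 (0.02) and Dnajb9 (-0.1). Of the 10, Hspa5 (0.52), Phgdh (0.91) and Psat1 (0.77) lost their calls without KO library 1 (0.41, 0.82 and 0.73), Hspa5 and Phgdh without KO library 2 (0.63 and 1.01) and Hspa5 without WT library 2 (0.41). Chac1 (1.44) gave 0.93 without WT library 1 and 2.22 without WT library 2. Germline genes silenced by DNA methylation went the other way: 5 of 16 were lower, among them Dazl (-1.79), Sycp1 (-1.75), Stk31 (-1.82) and Mael (-1.13), and 1, Rpl10l, was higher, with a median of -0.92 (camera adjusted p = 0.000183, and 0.429 with an estimated correlation). At a mean CPM of at least 10 that list did not pass (-0.77, adjusted p = 0.069). Adjusted over the list alone, 9 were lower and 1 higher. Without KO library 1 the calls of Sycp1 (-1.77), Stk31 (-1.58) and Mael (-0.85) were lost, and without KO library 2 those of Sycp1 (-1.72) and Rpl10l (0.86, and 0.61 without WT library 2). Tex101 (-4.36), the last of the 5, lost its call without KO library 1 (-6.57) or KO library 2 (-3.56). It did not pass the filter without WT library 1 or without WT library 2. Of the 5 tested genes of the 2-cell-like state, a rare state of cultured embryonic stem cells, Zscan4d (3.08) and Gm8300 (2.18) were higher (list median 2.00, camera adjusted p = 0.00633, and 0.652 with an estimated correlation, 4 of 5 higher adjusted over the list alone), and with the DESeq2 test the list did not pass (adjusted p = 0.0642). Their counts were at most 54 per library, paralogs can share reads, and Zscan4d lost its call without KO library 2 (2.22, edgeR adjusted p = 0.261), and Gm8300 without KO library 1 (2.22), KO library 2 (2.15) or WT library 2 (1.66). The number of lists higher in KO was 2, and 5 without KO library 1, 3 without KO library 2 and 4 without WT library 1. The number lower was 2, and 3 without KO library 2 or without WT library 2. With an estimated correlation, which rests on 2 residual degrees of freedom, none of the 26 lists passed.

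The other lists did not pass the camera test, and with an estimated correlation their adjusted p was at least 0.589. Of 16 core pluripotency genes, 4 were lower, among them Dnmt3l (-1.92, SE 0.17), a cofactor of DNA methylation, and Utf1 (-0.91), and 2 higher, among them the TGF-beta ligand gene Gdf3 (1.40) (list median -0.15, adjusted p = 0.394, 4 higher and 5 lower adjusted over the list alone). Of 19 naive pluripotency genes 3 were lower, among them the transcription factor gene Klf4 (-1.59), and 3 higher, among them Spp1 (1.40) (0.26, adjusted p = 0.63, 4 and 4). Of 14 formative and primed genes 3 were higher, among them Lef1 (3.58) and Sall2 (1.77), and 2 lower, Etv4 (-1.21) and Dnmt3b (-0.76) (0.03, adjusted p = 0.591, 5 and 3). Of 4 mesoderm and definitive endoderm markers 0 were called (median -0.94, adjusted p = 0.227, 0 and 1, with Mesp2 at -1.28 and an edgeR adjusted p of 0.0694). The direction of that list is not settled: its median was 1.04 without WT library 1 and 0.12 without WT library 2, with 7 members then tested. For neuroectoderm Pax6 was higher and Ncam1 (-1.20) lower of 8 (median -0.06, mean 0.20 and test direction higher, adjusted p = 0.948, 1 and 1). For trophectoderm 3 of 11 were higher, Tfap2c (1.78), Fgfr2 (2.52) and Gata2 (2.33), and Ascl2 was lower (-1.71) (median -0.09, mean 0.41 and test direction higher, adjusted p = 0.561, 4 and 2). Without KO library 1 the calls of Utf1 (-0.77), Etv4 (-0.96), Dnmt3b (-0.89), Ncam1 (-0.72), Gata2 (2.11) and Ascl2 (-1.56) were lost. Without KO library 2 those of Sall2 (1.53), Dnmt3b (-0.64) and Ascl2 (-1.86) were lost, while Ncam1 gave -1.90, and without WT library 1 those of Dnmt3b (-0.52) and Ncam1 (-0.93).

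In cell cycle lists, Cdkn2a (1.51, SE 0.22) and Cdkn1b (0.75, SE 0.20) rose among 10 genes of CDK inhibitors and pocket proteins (median 0.44, adjusted p = 0.0688, 3 higher and 0 lower adjusted over the list alone). That list passed without a low-count filter (adjusted p = 0.0326), without KO library 2 (adjusted p = 0.044) and without WT library 1 (adjusted p = 0.0282), and not without KO library 1 (adjusted p = 0.0782) or WT library 2 (adjusted p = 0.244). Of 25 E2F targets and replication genes 5 were lower, among them the transcription factor gene E2f2 (-0.96) and Ccne1 (-0.60), which encodes cyclin E1 (median -0.05, adjusted p = 0.457, 1 and 6). Of 23 p53 targets 5 were lower, among them the pro-apoptotic gene Pmaip1 (-1.90) and the antiproliferative gene Btg2 (-1.21), and 2 higher, Gdf15 (2.12) and Ei24 (median -0.50, adjusted p = 0.0744, 4 and 8), and the list gave -0.77 without WT library 2 (adjusted p = 0.00223) and -0.25 without WT library 1 (adjusted p = 0.41), and passed with the DESeq2 test (adjusted p = 0.0211). Of 21 apoptosis regulators 2 were higher, among them Bad (1.09) (median 0.02, mean -0.02 and test direction lower, adjusted p = 0.948, 3 and 1). Without KO library 1 the calls of Cdkn1b (0.73), Ccne1 (-0.62) and Bad (1.09) were lost. Without KO library 2 those of Cdkn1b (0.77), E2f2 (-0.85), Ccne1 (-0.56), Ei24 (0.71) and Bad (1.10) were lost, and without WT library 1 that of Cdkn1b (0.51).

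In signalling lists, 5 of 22 Nodal, TGF-beta and BMP genes were higher, including Lefty1, Lefty2 and Skil (1.16), and 2 lower, among them the ligand gene Bmp4 (-1.53, SE 0.14) (median 0.59, adjusted p = 0.111, 9 higher and 3 lower adjusted over the list alone). That list passed without a low-count filter (adjusted p = 0.0366), and gave 0.42 without KO library 1 (adjusted p = 0.0179), 0.30 without KO library 2 (adjusted p = 0.196) and 0.31 without WT library 2 (adjusted p = 0.226). Of 12 Wnt targets 4 were higher, among them Lef1, Notum (3.16), which encodes a Wnt deacylase, and Sp5 (2.87), and 1 lower (median -0.23, mean 0.33 and test direction higher, adjusted p = 0.948, 4 and 4). Sp5 lost its call without KO library 1 (2.91) or KO library 2 (2.83). Wwtr1 (1.17), a coactivator gene, was the 1 called of 16 in the Hippo pathway (0.10, adjusted p = 0.962, 1 and 0). Interferon response genes split: of 13, the transcription factor genes Irf1 (1.87) and Irf9 (1.10) and the antiviral genes Oasl2 and Ifit1 were higher, and 3 were lower, among them the antigen presentation genes Psmb9 (-2.20) and B2m (-1.19). Oasl2 (60 and 42 counts in KO) and Ifit1 (13 and 22) had 0 counts in WT and were at least 30.5-fold and 10.6-fold higher against the floor. Irf9 lost its call without KO library 1 (1.03) or KO library 2 (1.17), B2m without KO library 1 (-0.93) and Psmb9 without KO library 2 (-1.88), where Ifit1 was too low to test. The list median was -0.03, its mean 0.62 with the genes absent from WT at their bounds, and its test direction higher (adjusted p = 0.491, 5 and 3), and it passed without KO library 1 (median 1.06, adjusted p = 0.00934). Without KO library 2 the median was -0.38 (adjusted p = 0.97), and without WT library 1 or 2 it was 0.90 and 1.05 (adjusted p = 0.41 and 0.266), with 12 to 16 members tested.

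Among the remaining lists, Dnmt3l and the methyltransferase gene Dnmt3b were lower and Mbd2 higher of 10 DNA methylation genes (-0.05, adjusted p = 0.948, 1 higher and 3 lower adjusted over the list alone). Without KO library 1 the calls of Dnmt3b (-0.89) and Mbd2 (0.81) were lost, without KO library 2 likewise (-0.64 and 1.01), and without WT library 1 that of Dnmt3b (-0.52). Of 20 glycolysis genes 3 were lower, among them the enzyme gene Pgam1 (-1.05, and -0.89 without KO library 2, where the call was lost) (-0.18, adjusted p = 0.227, 0 and 5). Of 13 genes of the epithelial-mesenchymal transition 3 were lower, among them the metalloprotease gene Mmp2 (-1.61, and -1.18 without KO library 1, where the call was lost) (-0.21, adjusted p = 0.209, 1 and 3). Of 15 genes of the microRNA pathway, Ago1 (1.00) and Tnrc6a (0.57), which encode effector proteins of silencing, were higher, and 2 were lower, among them Lin28a (-0.84) (-0.11, adjusted p = 0.561, 2 and 3). Ago1 (0.85), Tnrc6a (0.49) and Lin28a (-0.64) lost their calls without KO library 2, and Tnrc6a (0.66) without KO library 1. The stress gene Atf3 (1.34) was higher of 15 immediate early and heat shock genes, though not without KO library 2 (1.01) (0.21, adjusted p = 0.407, 1 and 0). Of 8 mitochondrially encoded genes mt-Nd6 (-1.54) and mt-Nd2 (-0.70, and -0.60 without KO library 2, where the call was lost) were lower (-0.28, adjusted p = 0.202, 0 and 2), and mitochondrial genes took 5.08% and 4.93% of counts in KO and 6.02% and 5.58% in WT.

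**Figure D4:**
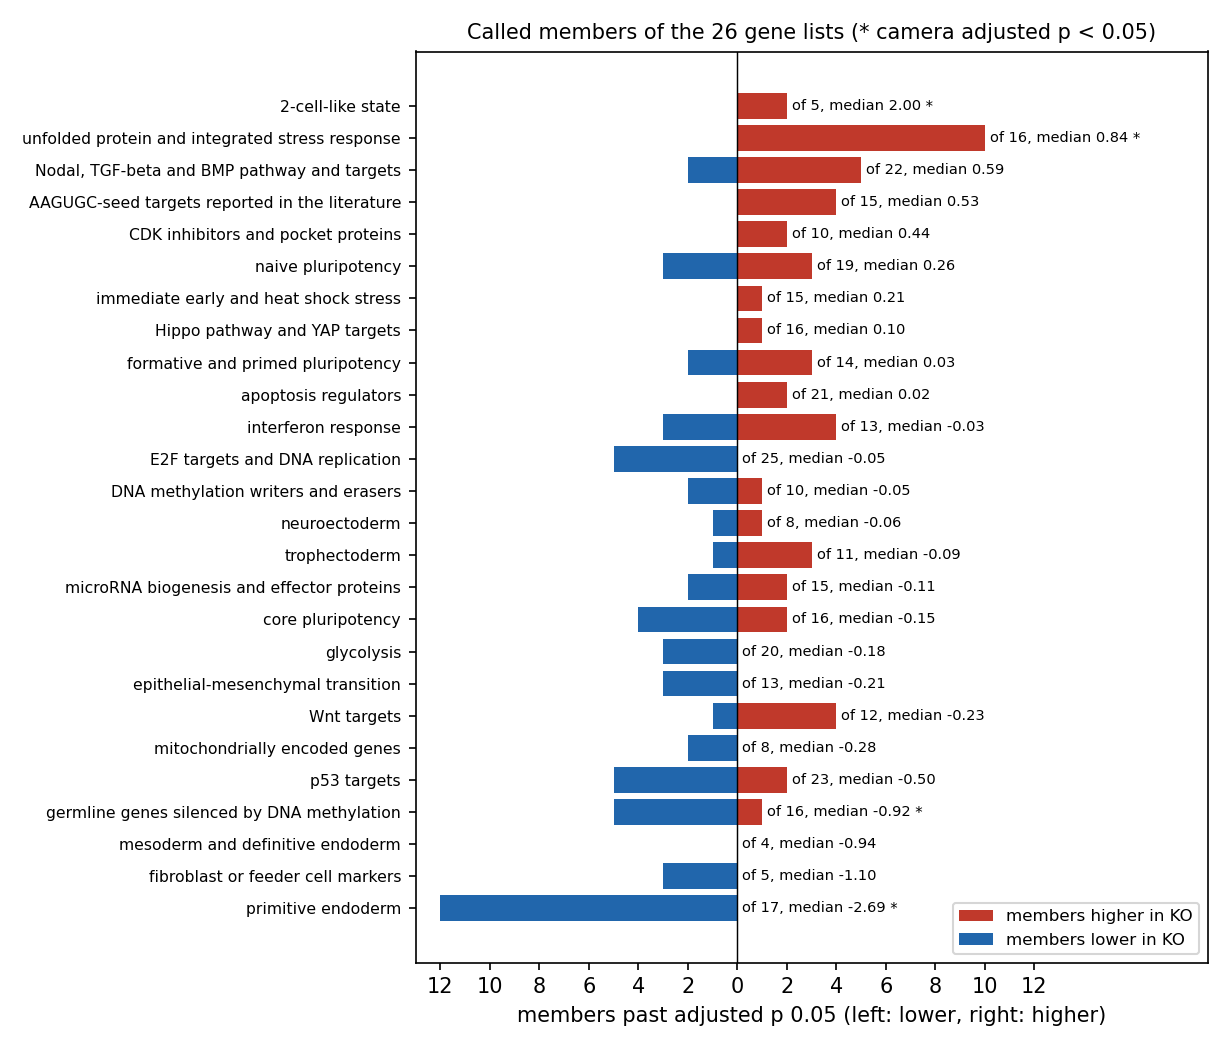
Number of members of each of the 26 lists that were lower (blue, left) or higher (red, right) in KO at an edgeR adjusted p below 0.05, with the number tested and the list median log2 fold change beside each bar. Stars mark the 4 lists past a camera adjusted p of 0.05, of which primitive endoderm has 12 lower members and the unfolded protein and integrated stress response 10 higher members.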

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

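Leaving out chromosome 1, removing chromosome medians and leaving out small non-coding and mitochondrial genes were chosen after the data were seen. No gene called in KO against WT changed direction under any alternative in which it was tested. With DESeq2 size factors, the DESeq2 test, thinning and those 3 added choices, the numbers of higher and lower genes stayed within 1.5 times of 1071 and 715. Without a low-count filter 1193 genes were lower, and with a mean CPM of at least 10, where 8711 genes were tested, 636 were higher and 391 lower. Leaving out 1 library gave 556 to 1477 higher and 285 to 1011 lower genes, with the lone library of a group assumed to vary like the other group. Lists higher in KO numbered 2 in the main test, 5 without a filter, 1 at a mean CPM of at least 10 (where 1 list was lower), 2 to 5 with 1 library left out, and 0 with an estimated correlation, which also left 0 lower. Lists lower numbered 2 to 3 with 1 library left out. The DESeq2 test gave 2 lists higher, with the literature targets in place of the 2-cell-like state, and p53 targets as an added lower list. With 1 library left out more genes passed the filter, so lists can hold other members. List medians then turned direction for 10 lists that did not pass besides interferon response: mesoderm and definitive endoderm (-0.74 to 1.04), neuroectoderm (-0.56 to 0.09), trophectoderm (-0.31 to 0.92), epithelial-mesenchymal transition (-0.75 to 0.16), Hippo (-0.35 to 0.53), apoptosis (-0.20 to 0.16), immediate early genes (-0.09 to 0.38), formative (-0.14 to 0.48), core pluripotency (-0.24 to 0.01) and DNA methylation genes (-0.13 to 0.15).

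The libraries share replicate numbers, which the labels do not tie to a batch, and the differences within the KO pair and within the WT pair correlated at -0.0703 across genes. With the replicate number as a block 638 genes were higher and 370 lower, with fewer residual degrees of freedom, and fibroblast or feeder cell markers were an added lower list (adjusted p = 0.0259).

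The seed site shift of 0.144 kept its direction in every alternative. It was no longer past the threshold without KO library 2 (0.126), with an estimated correlation (0.144, camera p = 0.0601), with 6-base sites alone (0.0669), the shortest 3' UTR (0.105), a background matched on 3' UTR length and expression (0.107) and chromosome medians removed (0.128). The shift ranged from 0.108 to 0.15 with 1 library left out. The cause of these changes was not tested. Genes that turned direction were all uncalled, Foxa2 and Sparc among them. AU018091 (0.01) gave 0 with DESeq2 size factors, the DESeq2 test and the replicate block, -0.02 at a mean CPM of at least 10 and with chromosome medians removed, -0.01 when thinned, and -0.15 to 0.16 with 1 library left out (-0.15 without KO library 1, -0.07 without WT library 2). With 1 library left out Eomes ranged from -0.88 to 1.46 (0.07 without KO library 2, 1.46 without WT library 2, and 0.20 with the block). Lats2 ranged from -0.64 (without KO library 2) to 0.88 (-0.19 without WT library 2), Zfp36 from -0.09 (without KO library 2) to 0.97, Kdr from -1.97 to 1.04 and Wee1 from -0.21 to 0.11 (both turned without WT library 1), and Rbl2 from -0.01 (without WT library 2) to 0.54. Of 132 named genes, 30 lost their call without KO library 1 and 33 of 131 without KO library 2, against 6 of 132 without WT library 1 and 6 without WT library 2. The named genes include some that were not called and so could not lose a call, such as Eomes and Wee1. The share of calls lost is therefore larger than these counts over all named genes. In the simulated counts with 200 genes changed, the test recovered 5.97% of 1.5-fold and 34.3% of 2-fold changes. The share missed in the real data, where more genes were called, was not measured.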

Other observations

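The tests on chromosome 1, on the WT libraries behind the endoderm markers and on Mir290b were chosen after the result was seen. The tests on a second endoderm list and on myeloid genes were written before those values were seen, and the use of an interval for the endoderm median was added afterwards.

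Of 74 genes of small nucleolar and Cajal body RNAs tested, 37 were lower in KO and 0 higher, and no set test was run on them. For the 68 that lie inside another tested gene on the same strand the median log2 fold change was -2.07, while the median of their 63 host genes was 0.01 and 2 of the hosts were lower. The 6 scaRNA genes were all lower, with a median of -3.10, and of 13 mitochondrial tRNA genes 8 were lower, with a median of -1.57. These RNAs have no poly(A) tail in their mature form. Genes of the Y chromosome differed between libraries of the same group: Ddx3y held 293 and 78 counts in KO and 1238 and 150 in WT, and Zfy1 held 0 and 0 in KO and 27 and 14 in WT.

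Among 575 genes of chromosome 1 with a log2 CPM above 3, 123 were higher in KO and 10 lower, and their median lay 0.3 above that of other autosomes (95% bootstrap interval 0.261 to 0.359). Genes without GCACTT shifted as much (0.293, interval 0.243 to 0.35), which argues against loss of seed repression as the cause, and adjustment for expression level, 3' UTR length and GC left 0.302 (0.26 to 0.347). The shift ran along the chromosome, with a median above 0.1 in 88.9% of 18 windows of 10 Mb. A copy number that differs between cultures may account for it, as a hypothesis. The shift was not even, with medians in these windows from 0.06 (positions 40000001 to 50000000) to 0.47 (170000001 to 180000000). It was larger against WT library 1 (0.41 and 0.46) than against WT library 2 (0.18 and 0.21), and WT library 1 over WT library 2 gave -0.28, a difference as large as that of KO from WT, which the bootstrap over genes does not measure. Chromosome 15 also differed between the WT libraries. Its KO medians were -0.26 and -0.25 against WT library 1 and -0.01 and 0 against WT library 2. There WT library 1 over WT library 2 gave 0.21, and on chromosome 6 it gave 0.14. DNA copy number was not analysed here, so a difference between cultures and an effect of the deletion itself both stay open.

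Primitive endoderm markers were lower in KO against each WT library, with a list median of -2.52 against WT library 1 and -2.35 against WT library 2, which argues against a single WT library as their source. A candidate explanation is a smaller share of endoderm-like cells among the KO cells. A second list of 18 extraembryonic endoderm genes, 13 of them tested, had a median of -0.50, below all but 0.36% of 10000 lists matched on expression. The median met the bound set for it by less than its error (95% bootstrap interval -0.88 to 0.67), and its members went both ways: Trf (-2.17), P4ha2 (-1.36, call lost without KO library 2, -0.93) and Nid2 (-0.60, call lost without KO library 1, -0.52, or KO library 2, -0.67) were lower and Serpinh1 (1.52), Lrp2 (1.09) and Cst3 (0.96) higher. Fewer such cells and lower expression of the first list within cells cannot be told apart, because the libraries are of whole cultures.

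Nlrp12, expressed in myeloid cells, held 161 counts in KO library 1 (95% Poisson interval 137 to 188) and at most 1 in the other libraries. Myeloid cells in that culture would bring other abundant transcripts, but 12 myeloid genes together held 28 counts there, against 37 in KO library 2, 60 in WT library 1 and 44 in WT library 2. The last exon of Nlrp12 lies antisense to the cluster, and Mir290b, on the same minus strand, held 4 counts in KO library 1 and 0 in the others. A rearranged allele in KO library 1, such as an inversion, may give such reads, and it cannot be told apart from other sources because the table gives no read positions.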
